A study of Mus musculus with 6 samples.

How the data were processed

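Tumour-associated macrophages were sorted from Lewis lung carcinoma tumours, a transplantable mouse lung cancer line grown under the skin of C57BL/6 mice and taken between day 15 and day 17. Per the labels' protocols, the sort took cells with CD11b and F4/80 and without Ly6C and Ly-6G, and divided them by surface MHC class II into a high and a low population. There were 6 libraries, 3 per label, each with a batch number from 1 to 3 that is also its replicate number. Total RNA was depleted of ribosomal RNA and made into stranded libraries, per the labels' protocols. Nothing in the labels says that the 3 libraries of a label came from separate mice, so the p-values measure the spread between these libraries, which may be technical.

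The deposited values are raw read counts per Ensembl gene, 1 table per library with 55487 genes and 5 summary lines of reads assigned to no gene. The submitters' processing notes name FastQC, Trimmomatic, STAR, HTSeq, DESeq2 and the GRCm38 build, without versions. The annotation release and the strand setting of the counting are not given in the sources used here. Without the strand setting, reads of a gene and of a transcript antisense to it cannot be told apart, and values of overlapping genes are uncertain. Reads assigned to no feature made up 35.2% to 49.4% of the listed reads of a library, ambiguous reads 0.324% to 0.864% and reads aligned to several places 7.6% to 17.4%. These stayed out of library sizes and tests.

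Gene symbols, types and coordinates came from GENCODE M21 on GRCm38, which matched 55227 of the 55487 genes. lncRNAs were the genes of its long non-coding types, with genes of type TEC (to be experimentally tested) left out. Some genes of these types carry names of protein-coding genes, such as Cct6a, Ifi30 and Ptpmt1, and were counted as lncRNAs. The counts were tested in R 4.3.3 with edgeR 4.0.16. TMM factors were computed, genes were kept by the default filter on low counts, and the quasi-likelihood test compared the libraries labelled MHC-II high with those labelled MHC-II low, without further terms. Genes past a Benjamini-Hochberg adjusted p of 0.05 were called. The test covered 14140 genes, of which 11626 were protein-coding and 824 were lncRNAs. CPM values are the deposited counts divided by TMM-scaled library sizes, given as mean ± SD over 3 libraries. Fold changes are log2 values of labelled high over labelled low, so that a negative value is lower in the libraries labelled MHC-II high, and their standard error is the fold change divided by the square root of the test's F.

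The designs, the gene lists and most alternatives were fixed before the data were examined. There were 37 lists, and 33 with at least 3 tested genes went through camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists. Beside it stood camera with an estimated correlation and fry. The lists cover the flow gate, MHC class II and class I presentation, macrophage core genes, dendritic, plasmacytoid and monocyte markers, alternative and inflammatory activation, both interferon responses, hypoxia, glycolysis, oxidative phosphorylation, lipid-associated genes, cholesterol synthesis, matrix remodelling, chemokines, receptors, checkpoints and complement. They also cover transcription factors, cell cycle, neutrophils, T and NK cells, B cells, mast cells and eosinophils, fibroblasts, endothelium, epithelium, erythroid cells, dissociation stress, the unfolded protein response, mitochondrial mRNAs, ribosomal proteins, histones and lncRNAs with described roles. The share of lncRNAs called was compared with that of protein-coding genes by a two-sided Fisher exact test. It was also compared within 4 bins of abundance, cut at the quartiles of the lncRNAs, by an exact Cochran-Mantel-Haenszel test.

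The genes named were those of the flow gate with H2-Aa, H2-Ab1, H2-Eb1 and Cd74, and in each direction the 10 protein-coding genes with the largest fold change among those called, at no less than 5 CPM in the higher label and with the same direction in all 3 batches. In each direction 5 lncRNAs followed the same rule at 1 CPM, filled up by the smallest p where fewer were called. From each list up to 4 members with the smallest p at 1 CPM or more could be named. Genes outside this rule are said to have been chosen after their values were seen.

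Alternatives were RLE size factors, total counts, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter at 1 CPM in 3 libraries, the batch as a block, removal of rRNA and mitochondrial genes, and leaving out each library in turn. Added after the data had been seen were leaving out batch 3, sample quality weights in limma-voom, robust priors, a GC offset alone and with the block, and, for the comparison of cell type markers, a wider set of 9 other lists. The GC offset took out each library's smooth trend of log2 CPM over the GC content of a gene's longest transcript, by a local regression with a span of 0.4. The labels give the pairs of libraries a shared batch, so the numbers pair them. The deviations of paired libraries from their label means correlated over genes at 0.159, 0.335 and -0.116 in batches 1, 2 and 3. Combinations of unlike number ranged from -0.489 (labelled high 1 with labelled low 2) to 0.353 (labelled high 1 with labelled low 3).

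The test was run on simulated counts with the mean levels and sizes of these libraries, their trend of spread over abundance, and 200 changed genes. Spread particular to single genes or to a single library was not simulated, so recovery on the real counts may differ. edgeR recovered 28% of the 2-fold and 98% of the 4-fold changes, with 3 false calls among 13922 genes tested. With the trends over GC content of these libraries added to the simulation, edgeR recovered 13% and 74%, and with the GC offset 26% and 95% with 4 false calls among 13924. The simulated spread came from counts that already held these trends, so the trends entered both through the spread and through the means. They were planted with the same kind of smooth that the offset takes out, and the changed genes were drawn without regard to GC content. A gain with the offset was thus largely fixed in advance. Pairs of libraries of one label differed far beyond sampling noise, with a chi-square of 12.75 to 754.9 per degree of freedom, so no library was counted as a copy of another. Library depth was 10202879 to 25473051 reads in genes.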

Results

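The transcriptomes of 2 populations of tumour-associated macrophages from Lewis lung carcinoma were measured by rRNA-depleted total RNA sequencing, with 3 libraries labelled MHC-II high and 3 labelled MHC-II low. Reads in genes numbered 15159356, 20167830 and 25473051 in the libraries labelled MHC-II high and 17292265, 21290781 and 10202879 in those labelled MHC-II low, for replicates 1, 2 and 3. The comparison asked which genes, and which lncRNAs among them, differ between macrophages sorted by surface MHC class II. The library labelled MHC-II low replicate 3 stood apart. An rRNA copy, CT010467.1, took 47.3% of its reads in genes, against 13.5% in labelled low replicate 1 and 3.85% to 5.17% in the other 4 libraries. That library kept 4669283 reads outside rRNA and mitochondrial genes, against 11670849 to 17982808 elsewhere, and 17858 genes had a read, against 20981 to 21636. Its log2 CPM correlated with those of the other libraries at 0.903 to 0.953 over genes, and the first principal component, with 60.1% of the variance, separated it from them.

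**Figure D1:**
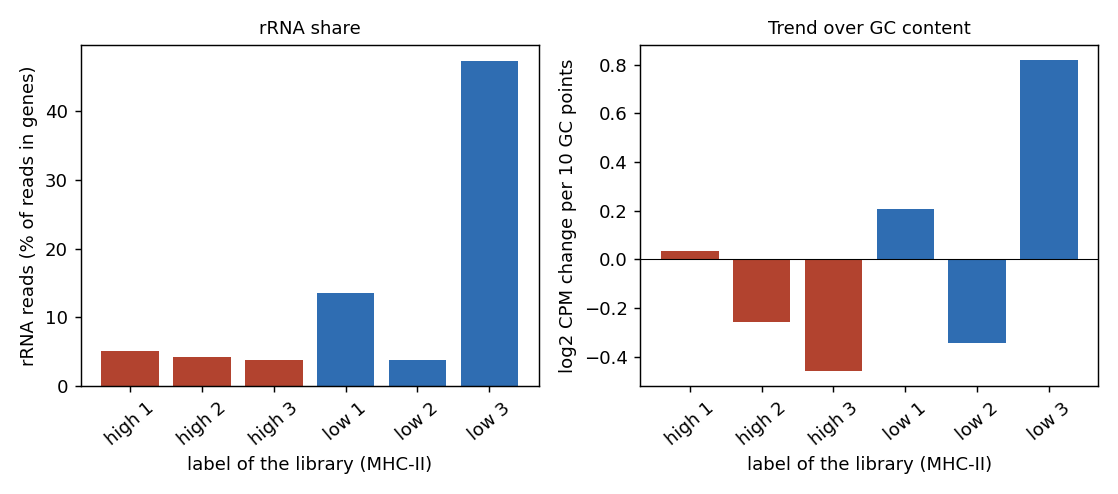
Left, share of reads in genes taken by an rRNA copy in each library, in percent. Right, slope of log2 CPM over the GC content of genes, relative to the mean of all 6 libraries, per 10 percentage points of GC. Red bars are libraries labelled MHC-II high and blue bars those labelled MHC-II low; labelled low replicate 3 reaches 47.3% and 0.82.

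Transcripts of MHC class II, the surface protein by which the cells were divided, went against the labels in all 6 libraries. H2-Aa, the alpha chain of the I-A molecule on chromosome 17 from 34282744 to 34287823 (GRCm38), stood at 5.52 ± 1.15 CPM in the libraries labelled MHC-II high and at 1350 ± 172 CPM in those labelled low (SD, n = 3 each). This was a log2 fold change of -7.93 with a standard error of 0.28 and an adjusted p of 2.594e-05 by edgeR. H2-Ab1, the partner chain, stood at 25.6 ± 0.80 and 1570 ± 549 CPM, and H2-Eb1, a chain of the I-E molecule, at 2.20 ± 0.38 and 711 ± 176 CPM. Cd74, the invariant chain that chaperones MHC class II, stood at 30.6 ± 4.9 and 3049 ± 1318 CPM. Ciita, the transactivator of these genes, stood at 0.985 ± 0.42 and 86.8 ± 33 CPM. The log2 ratios of H2-Aa within batches 1, 2 and 3 were -8.28, -7.73 and -7.81. Of the 11 tested genes of MHC class II presentation, 9 were lower in the libraries labelled MHC-II high and 10 were lower and 1 higher when adjusted over the list alone. The exception was Ctss, the protease cathepsin S, at 1981 ± 38 CPM in the libraries labelled high and 1261 ± 160 CPM in those labelled low, which did not pass over all genes (adjusted p 0.242 by edgeR) and was named after its values were seen. The adjusted p of the list by camera was 2.49e-106, and it was 0.00545 with an estimated correlation. Because of this contradiction the groups are named by their labels throughout, and each direction below is that of the libraries as labelled.

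**Figure D2:**
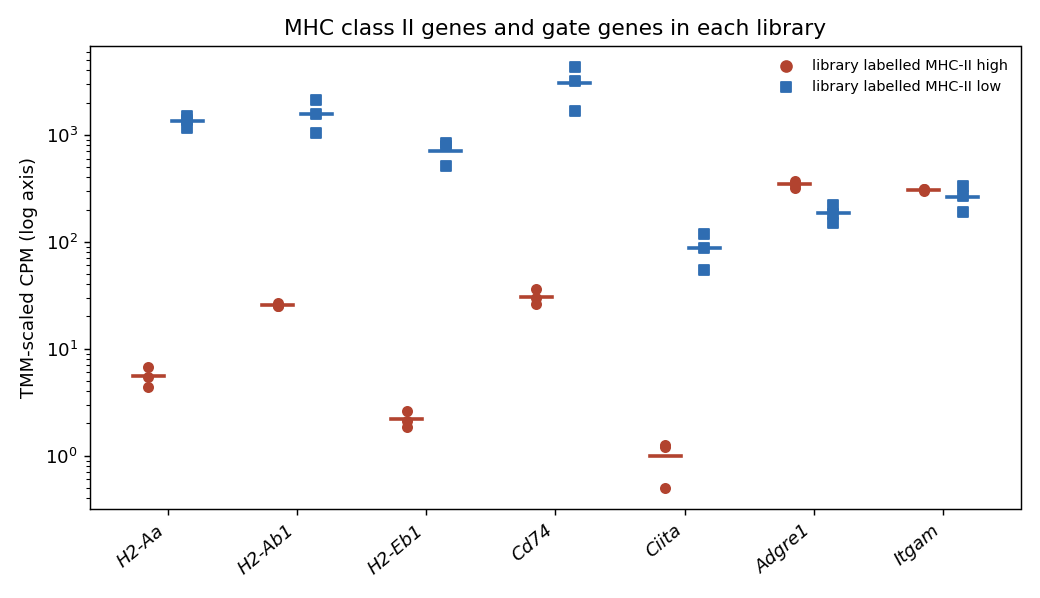
TMM-scaled CPM on a log axis of MHC class II genes and of 2 genes of the flow gate in each of the 6 libraries. Points are libraries and horizontal bars the mean of 3; for the first 5 genes every library labelled MHC-II low lies above every library labelled MHC-II high.

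Neither of the 2 tested genes of the flow gate passed the test by edgeR. Adgre1, which encodes F4/80, stood at 344 ± 26 CPM in the libraries labelled MHC-II high and 184 ± 34 CPM in those labelled low, with an adjusted p of 0.132 by edgeR and of 0.0169 with the GC offset. Itgam, which encodes CD11b, stood at 307 ± 8.2 and 265 ± 71 CPM, with an adjusted p of 0.633. Ly6c1 and Ly6c2 were too low to test, with 8 and 19 reads in total under the high label and 26 and 21 under the low label, and Ly6g had 0 reads in all 6 libraries. Of the 2 tested genes 1 was higher when adjusted over the list alone.

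Among 14140 genes, 50 were lower and 13 were higher in the libraries labelled MHC-II high by edgeR. All 63 went in one direction in the 3 batches, which selection on the same libraries favours, as did 5674 of all tested genes (40.1%), and all 63 had a fold change of at least 1 on the log2 scale. Beside the MHC class II genes, the largest decreases among called protein-coding genes of at least 5 CPM under the low label were in Ear2, Retnla, Klrb1b, P2ry10 and Ccl22. Below that level, Ccr7 had a log2 fold change of -7.77. Retnla, an alternative activation gene that encodes RELM-alpha, stood at 0.560 ± 0.13 CPM in the libraries labelled high and at 39.9 ± 18 CPM in those labelled low (log2 fold change -6.15, standard error 0.43, adjusted p 0.000731). Ccl22, a chemokine made by dendritic cells and macrophages, stood at 0.586 ± 0.089 and 12.3 ± 1.5 CPM (log2 fold change -4.36, standard error 0.28). Klrb1b, a lectin-like receptor best known from natural killer cells, stood at 0.120 ± 0.084 and 5.25 ± 2.4 CPM. P2ry10, a lysophospholipid receptor gene, stood at 0.405 ± 0.16 and 9.90 ± 4.9 CPM. Ear2, an eosinophil-associated ribonuclease with close paralogs that can share reads, had 6 reads in total under the high label and 360 under the low label.

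The 13 higher genes were led by Fgf2, fibroblast growth factor 2, on chromosome 3 from 37348346 to 37410108. It stood at 8.50 ± 1.4 CPM in the libraries labelled MHC-II high and 1.44 ± 0.28 CPM in those labelled low, 5.97-fold higher, with a log2 fold change of 2.58, a standard error of 0.29 and an adjusted p of 0.0161 by edgeR. Pdpn, the membrane glycoprotein podoplanin, stood at 313 ± 42 and 123 ± 13 CPM, and Serpinb6a, a serine protease inhibitor, at 296 ± 11 and 107 ± 30 CPM. Htr2b, a serotonin receptor gene, stood at 7.07 ± 1.3 and 1.66 ± 0.40 CPM, and Ptprm, a receptor tyrosine phosphatase, at 10.9 ± 1.2 and 2.86 ± 0.32 CPM. Rasgrp3 and Rapgef5, exchange factors of small GTPases, had log2 fold changes of 1.70 and 1.41. The log2 fold changes of Sh3bp5, Sh3bgrl2 and D330045A20Rik were 1.37, 1.27 and 2.11. With the batch as a block, Fgf2 was the only one of the 13 still past the threshold (adjusted p 0.0392), the others lying between 0.0501 and 0.158, and 40 genes were lower.

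The libraries also differed in a trend over GC content. Labelled low replicates 3 and 1 had the steepest rise of CPM with the GC content of genes, 0.82 and 0.21 per 10 percentage points on the log2 scale, against -0.46 to 0.03 in the other 4 libraries. Over 14123 genes, which are not independent replicates, the fold change between labels had a Spearman correlation of -0.58 with GC content. With the GC offset edgeR gave 135 higher and 246 lower genes, and with the GC offset and the batch block 200 higher and 391 lower. Both held all 13 and all 50 genes of the test without it. Without labelled low replicate 2, 246 genes were higher and 784 lower, but the labels then also parted the libraries by the trend over GC content. Without any one of the labelled high replicates or labelled low replicate 1, 0 were higher and 8 to 14 lower. DESeq2 gave 121 higher and 277 lower genes, including all 63.

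Dendritic cell marker genes were lower in the libraries labelled MHC-II high. Of 15 tested, 4 were called, 14 were lower when adjusted over the list alone, and the median log2 fold change was -2.15. Camera gave an adjusted p of 1.89e-30, and of 0.00545 with an estimated correlation. Itgax, which encodes the integrin CD11c, stood at 61.3 ± 23 CPM in the libraries labelled high and 304 ± 74 CPM in those labelled low. Flt3, a receptor needed for dendritic cell development, had 8 reads in total under the high label and 186 under the low label. Ccr7, the chemokine receptor that guides migration to lymph nodes, had 1 read under the high label and 229 under the low label. Ccl22 was the last of the 4. The median of the list was -1.92 with the GC offset, which called 9 of the 15, and -1.96 over the same 15 without labelled low replicate 3. Of the 5 tested plasmacytoid dendritic cell markers 0 were called (adjusted p 0.619 by camera).

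**Figure D3:**
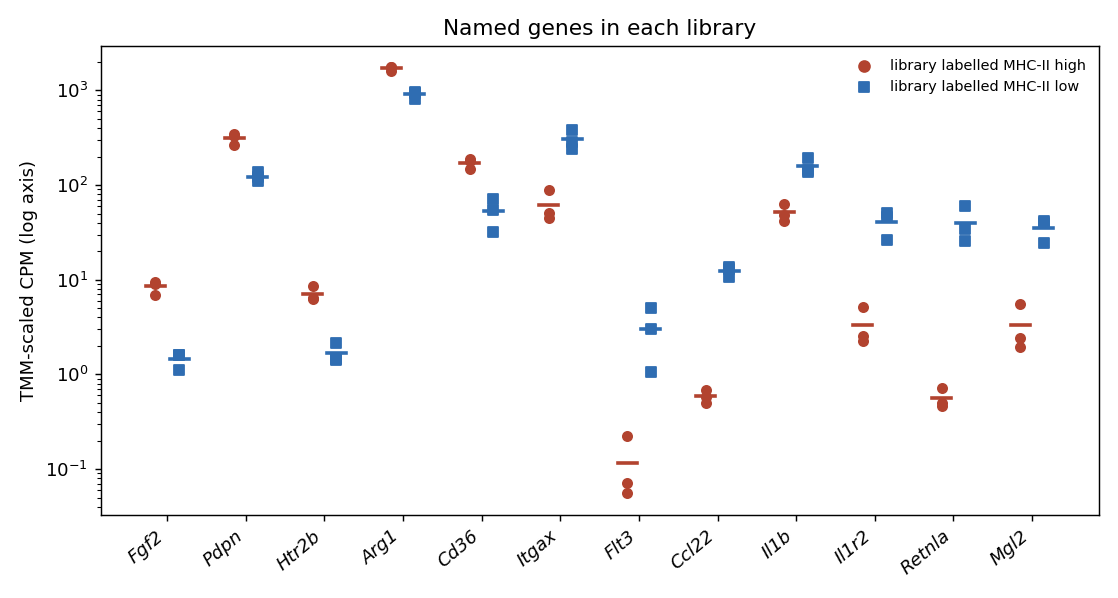
TMM-scaled CPM on a log axis of 12 named genes in each of the 6 libraries. Points are libraries and horizontal bars the mean of 3; Arg1 (adjusted p 0.0966) and Cd36 (0.0655) did not pass the threshold, and the other 10 did.

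Few markers of lymphocytes and granulocytes were high enough to test. Of the 3 tested B cell markers 0 were called and 3 were lower when adjusted over the list alone, with a camera adjusted p of 0.000107 and an adjusted p of 0.101 with an estimated correlation. By fry the adjusted p of this list was 0.00127. Ighm, an immunoglobulin heavy chain, stood at 1.43 ± 0.23 CPM in the libraries labelled high and 6.87 ± 3.3 CPM in those labelled low. Of the 2 tested T and NK cell markers 0 were called, and 1 was lower when adjusted over the list alone. Of the 2 tested markers of mast cells, basophils and eosinophils 1, Ear2, was lower. Of 4 neutrophil markers 0 were called (adjusted p 0.619), as were 0 of 13 fibroblast (0.11) and 0 of 5 endothelial markers (0.97), and no erythroid gene could be tested. Cdh1, which encodes E-cadherin, was the only 1 of 6 epithelial markers called, at 10.3 ± 1.2 and 33.9 ± 3.7 CPM (list adjusted p 0.248). The fibroblast list passed the threshold, on the lower side, with the block (adjusted p 0.0341), with the GC offset and the block (0.0373), with total counts (0.0121), and without labelled high replicate 1 (0.0291), labelled high replicate 2 (0.00796) or labelled low replicate 3 (0.00285). It did not with the GC offset alone (0.227), by fry (0.5) or with an estimated correlation (adjusted p 0.743). The epithelial list passed without labelled low replicate 3 (0.017) but not by fry (0.345) or with an estimated correlation (adjusted p 0.719). Adjusted over the list alone, 1 plasmacytoid, 1 endothelial and 1 epithelial marker and 0 neutrophil and fibroblast markers were lower.

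The list of the response to interferon gamma was on the lower side by camera in the libraries labelled MHC-II high (adjusted p 6.84e-07), with a median log2 fold change of -0.293, 2 of 20 genes called and 6 lower when adjusted over the list alone. Its adjusted p was 0.287 with an estimated correlation and 0.0281 by fry. The 2 called genes were Ciita and Gbp8, an interferon-induced GTPase gene, the latter at 1.23 ± 0.58 and 7.57 ± 1.3 CPM (adjusted p 0.0396, and 0.0609 with the block). Chemokine and cytokine receptors were lower as a list (2 of 28 called, 5 when adjusted over the list alone, adjusted p 2.72e-05, 0.0696 as the adjusted p with an estimated correlation, and 0.00127 by fry). Il1r2, the decoy receptor of interleukin 1, stood at 3.33 ± 1.6 CPM in the libraries labelled high and 40.9 ± 13 CPM in those labelled low. Inflammatory activation genes were lower as a list (1 of 19 called, 2 when adjusted over the list alone, adjusted p 0.00578, 0.176 as the adjusted p with an estimated correlation, and 0.0281 by fry). Il1b, interleukin 1 beta, stood at 51.4 ± 11 and 158 ± 30 CPM (adjusted p 0.0311 by edgeR and 0.0742 with the block).

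Further lists were past the threshold with few or no single genes called. On the lower side by camera in the libraries labelled high were the lists of dissociation stress (1 of 24 called, adjusted p 0.000107), MHC class I presentation (0 of 16, 0.00132), monocyte markers (0 of 13, 0.00135), myeloid transcription factors (0 of 37, 0.0139) and matrix remodelling (0 of 25, 0.0281). None of the 5 passed with an estimated correlation, where their adjusted p values were 0.719, 0.719, 0.176, 0.719 and 0.719 in that order, and by fry only the monocyte list did (adjusted p values of 0.335, 0.335, 0.0348, 0.421 and 0.348). The cell cycle list was on the higher side by camera with 0 of 30 genes called (adjusted p 0.0139), and its adjusted p was 0.743 with an estimated correlation and 0.481 by fry. The called stress gene was Btg2, an anti-proliferative gene, at 55.3 ± 2.3 and 113 ± 6.1 CPM (adjusted p 0.0401, and 0.179 with the block). The median log2 fold change of MHC class I presentation was -0.718, but -0.304 without labelled low replicate 3 and -0.214 with the GC offset. For dissociation stress these medians were -0.518, -0.291 and -0.129, and for monocyte markers -1.01, -0.779 and -0.72. These lists stayed past the threshold by camera in both settings. With the GC offset the adjusted p of the transcription factors was 0.102 and that of matrix remodelling 0.383, and with the block added they were 0.0492 and 0.254. Both also missed the threshold without labelled low replicate 3 (0.121 and 0.142) or without labelled high replicate 2 (0.12 and 0.0536). The cell cycle list missed it without labelled high replicate 3 (0.24) or labelled low replicate 1 (0.176). Adjusted over the list alone, 1, 2, 0, 3, 1 and 0 genes of these lists were lower, and 1 transcription factor was higher.

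**Figure D4:**
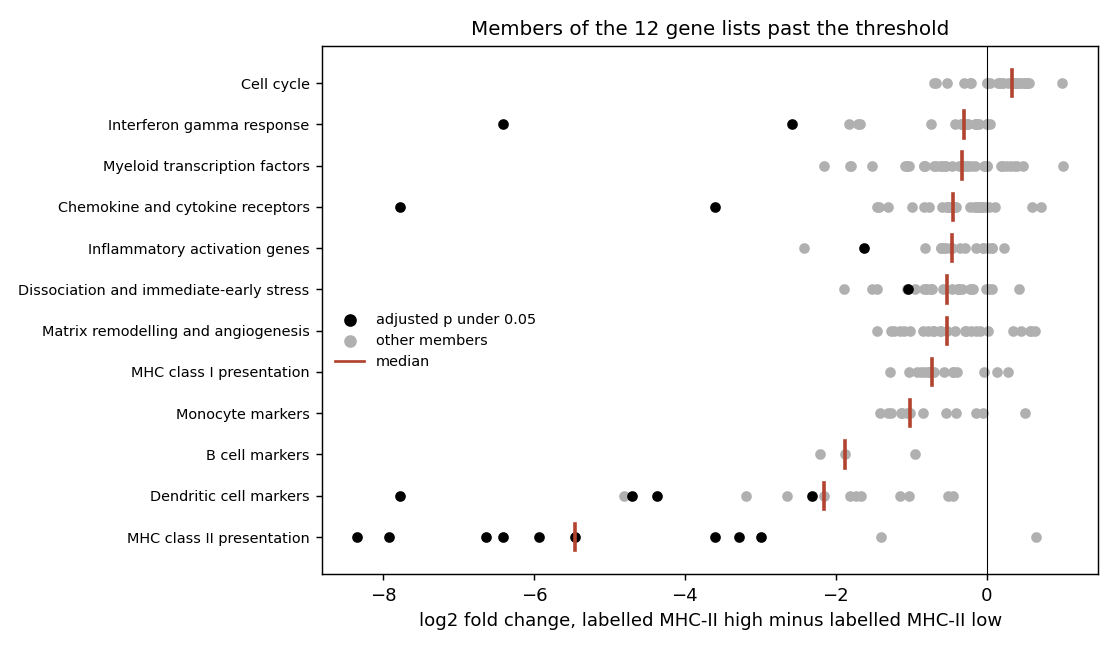
Log2 fold changes (labelled MHC-II high minus labelled MHC-II low) of the tested members of the 12 lists past the threshold by camera. Black points had an adjusted p under 0.05, grey points did not, and red bars are medians, from -5.46 for MHC class II presentation to 0.34 for the cell cycle.

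Alternative activation and scavenger genes moved both ways (2 of 22 lower, camera adjusted p 0.187, 0.022 with the block, 0.0373 with the GC offset and the block, 0.00563 with total counts, and 0.0465 and 0.00722 without labelled high replicate 1 or labelled low replicate 2), and 5 were higher and 4 lower when adjusted over the list alone. The list did not pass with an estimated correlation (adjusted p 0.743), by fry (0.524), with the GC offset alone (0.301) or without labelled low replicate 3 (0.31). Retnla and Mgl2, a macrophage lectin, were the 2 lower genes, the latter at 3.29 ± 1.9 and 35.1 ± 9.1 CPM. Arg1, the arginine-degrading enzyme arginase, stood at 1706 ± 80 CPM in the libraries labelled MHC-II high and 908 ± 86 CPM in those labelled low, with an adjusted p of 0.0966 by edgeR and 0.0066 with the GC offset. Cd36, a scavenger receptor for oxidised lipids, stood at 172 ± 21 and 52.9 ± 20 CPM, with an adjusted p of 0.0655 and of 0.0166 with the GC offset. Of 21 chemokines 1, Ccl22, was lower, while 3 were higher and 5 lower when adjusted over the list alone (camera adjusted p 0.11, 0.019 with the GC offset, 0.00971 with the offset and the block, 0.0152 and 0.0418 without labelled high replicate 3 or labelled low replicate 3, 0.335 by fry, and an adjusted p of 0.719 with an estimated correlation). Ccl2 and Ccl7, which attract monocytes, stood at 157 ± 9.7 and 90.5 ± 7.0 CPM under the high label and at 84.4 ± 7.7 and 38.0 ± 11 CPM under the low label, with adjusted p values of 0.0824 and 0.0962.

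Of 18 macrophage core genes 0 were called and 2 were higher when adjusted over the list alone (camera adjusted p 0.48). Lyz2, which encodes lysozyme, stood at 6456 ± 562 and 3384 ± 264 CPM (adjusted p 0.122, and 0.0116 with the GC offset). Metabolic lists had 0 genes called, with camera adjusted p values of 0.327 for 22 hypoxia genes, 0.326 for 17 glycolysis enzymes, 0.342 for 32 oxidative phosphorylation genes, 0.686 for 20 lipid-associated genes and 0.284 for 20 genes of cholesterol synthesis. The same held for the type I interferon response (22 genes, 0.117), checkpoint ligands and receptors (16 genes, 0.183), complement (10 genes, 0.278), the unfolded protein response (19 genes, 0.363), mitochondrial mRNAs (12 genes, 0.686), ribosomal proteins (41 genes, 0.619) and histones (17 genes, 0.342). The adjusted p of the type I interferon response was 0.019 with the GC offset, 0.00429 with the offset and the block, 0.00294 and 0.0377 without labelled high replicate 3 or labelled low replicate 2, 0.466 by fry, and 0.743 as the adjusted p with an estimated correlation. Without labelled low replicate 2 the lists of macrophage core genes (0.0345), glycolysis (0.0132), checkpoints (0.0406), complement (0.00832) and histones (0.027) also passed. In that setting the labels also parted the libraries by GC trend and rRNA share. With the GC offset and all libraries these lists did not pass by camera (adjusted p 0.458, 0.227, 0.0723, 0.666 and 0.662 in that order). Adjusted over the list alone, the 12 lists from hypoxia to histones held 1, 0, 0, 2, 0, 0, 0, 0, 1, 0, 0 and 0 higher genes and 1, 1, 0, 2, 1, 0, 5, 0, 0, 0, 0 and 0 lower genes in the order given.

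Of 824 lncRNAs, 1 was higher and 0 were lower in the libraries labelled MHC-II high by edgeR. At an unadjusted p under 0.05 there were 32 higher and 43 lower, and DESeq2 called 5 and 8. The lncRNA was 4930440I19Rik, on chromosome 2 from 78051177 to 78194430, at 3.75 ± 0.51 CPM in the libraries labelled high and 0.839 ± 0.20 CPM in those labelled low. Its log2 fold change was 2.18 with a standard error of 0.34 and an adjusted p of 0.0435, which was 0.107 with the block, and 0 lncRNAs passed when adjusted over lncRNAs alone. Mir99ahg, the host transcript of a microRNA cluster, stood at 9.94 ± 0.64 and 2.65 ± 1.6 CPM with an adjusted p of 0.14, and AI427809, 4930555A03Rik and Gm10484 had log2 fold changes of 1.13, 1.70 and 0.85. On the lower side and also short of the threshold, the log2 fold changes of 1700016P03Rik, 6530402F18Rik, Gm6209 and AW112010 were -2.13, -1.72, -1.43 and -1.42. Gm10484 overlaps Cdk14 and 6530402F18Rik overlaps Ntng2 on the same strand, and these genes had log2 fold changes of 0.64 and -2.06. Their reads can count toward the overlapping lncRNA, so both lncRNA values are uncertain. Gm15564 stood at 149 ± 14 and 1616 ± 2010 CPM, where labelled low replicate 3 was at 3930 CPM and replicates 1 and 2 at 628 and 292 CPM. These levels follow the order of the rRNA share, 47.3%, 13.5% and 3.87% in labelled low replicates 3, 1 and 2. Whether rRNA reads count toward Gm15564 was not tested. The log2 fold change of Gm15564, -3.44, was -1.63 without labelled low replicate 3, and its adjusted p of 0.194 was 0.00986 without labelled low replicate 2. Of 41 lncRNAs with described roles 0 were called, also when adjusted over the list alone (camera adjusted p 0.379, 0.0362 without labelled low replicate 2, and 0.689 with the GC offset).

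With the GC offset edgeR called 3 lncRNAs higher and 4 lower, and with the offset and the block 4 and 12. The 3 were Mir99ahg (adjusted p 0.013), 4930440I19Rik (0.0212) and Gm16104, an antisense gene (0.0207). The 4 were Gm6209 (0.0139), 1700016P03Rik (0.0209), AW112010, an interferon-inducible transcript (0.0284), and Mir17hg, another microRNA host transcript (0.0302). Gm16104 and Mir17hg were chosen after their values were seen. Of the lncRNAs 0.121% were called (exact 95% interval 0.00307% to 0.674%), against 0.516% of 11626 protein-coding genes (0.394% to 0.664%). The odds ratio was 0.234 with a two-sided Fisher exact p of 0.188, and within bins of abundance the odds ratio was 0.146 with an exact p of 0.0267. Both rest on 1 called lncRNA, and genes are not independent replicates. The highest bin reached from the upper quartile of the lncRNAs to the most abundant lncRNA, so abundance was not matched within it. With the GC offset the odds ratio was 0.267 with a Fisher exact p of 4.1e-05, and DESeq2 calls gave 0.485 with 0.00659, and 0.412 with an exact p of 0.00108 within bins of abundance. The median abundance was 1.38 CPM for lncRNAs and 18.3 CPM for protein-coding genes. Whether lncRNAs were called less often than protein-coding genes of like abundance is therefore not decided by these ratios.

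Of the other gene types, 2 genes were lower in the libraries labelled MHC-II high. Mir5107, on chromosome 18 from 60812076 to 60812163, lies within Cd74 on the same strand, and Gm37347, on chromosome 1 from 40088511 to 40091581, lies within Il1r2 on the same strand. Reads of the host gene can count toward either, so both were read as uncertain, and both were named after their values were seen.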

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

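The alternatives without batch 3, with quality weights, with robust priors and with the GC offset were chosen after seeing the data. RLE size factors, limma-voom, a filter at 1 CPM in 3 libraries, removal of rRNA and mitochondrial genes and robust priors kept both gene counts within 1.5 times of 13 and 50. H2-Aa, H2-Ab1, H2-Eb1, Cd74, Ciita, Retnla and Ccl22 were past the threshold in all 20 alternatives, and no named gene past the threshold changed direction. Higher and lower genes numbered 8 and 52 with total counts, 121 and 277 with DESeq2, 113 and 436 without a filter, 1 and 40 with the replicate block, and 45 and 193 with DESeq2 and the block. They numbered 0 and 28 without batch 3, 135 and 246 with the GC offset, 200 and 391 with the GC offset and the block, and 2883 and 3207 with quality weights. These weights gave labelled low replicate 1 a weight of 6.51 and labelled low replicate 2 one of 0.255, estimated from the same 6 libraries. Leaving out one library gave 0 to 246 higher and 8 to 784 lower genes. The highest counts came without labelled low replicate 2, and without labelled low replicate 3 there were 15 and 55.

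lncRNAs higher and lower in the libraries labelled MHC-II high numbered 0 and 0 with limma-voom, the block or without batch 3. They numbered 1 and 1 with total counts, 5 and 8 with DESeq2, 3 and 3 with DESeq2 and the block, 6 and 14 without a filter, 3 and 4 with the GC offset, 4 and 12 with the offset and the block, and 129 and 123 with quality weights. Leaving out one library gave 0 to 6 higher and 0 to 9 lower. The odds ratio of lncRNA calls was 0 with the block (p = 0.11), 0.267 with the GC offset (exact p = 4.1e-05) and 0.406 with the offset and the block (exact p = 7.9e-05). Camera with an estimated correlation left 0 higher and 2 lower lists, MHC class II presentation and dendritic cell markers, and fry 0 and 7. Leaving out one library gave 0 to 2 higher and 11 to 19 lower lists, the most without labelled low replicate 2. The cause of these changes was not tested. Fewer libraries enter where one is left out, which does not account for the rise without labelled low replicate 2, to 246 higher and 784 lower genes. Without it, the labels also parted the libraries by GC trend and by rRNA share. Labelled low replicates 1 and 3 had slopes of 0.21 and 0.82 per 10 percentage points, against -0.46 to 0.03 in the libraries labelled high. Their rRNA shares were 13.5% and 47.3%, against 3.85% to 5.17%. The added calls can therefore not be told apart from these differences. The simulation with trends over GC content recovered more changes with the GC offset (26% against 13% of the 2-fold changes), but its trends also entered through the spread. They were planted with the same kind of smooth that the offset takes out. The gain therefore does not bear on whether the added calls in the real counts are right. Of 152 named genes 13 lost their call with the block and 0 gained one; with the GC offset 0 lost and 27 gained one. The block took past the threshold the lists of alternative activation and of fibroblast markers and changed no other list. Total counts moved the median log2 fold change of all genes from -0.02 to 0.25, so directions of small changes are relative to the typical gene. In the simulation without such trends edgeR recovered 2 of 22 2-fold changes at 1 to 5 CPM and 23 of 54 above 20 CPM, and 18 of 19 4-fold changes at 1 to 5 CPM. Lower levels were not simulated, and the median lncRNA was at 1.38 CPM.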

Other observations

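The tests of exchanged labels, of B cells, of the macrophage share and of dendritic cells in the gate, their values without single libraries, the share of genes without overlap in other splits, and all tests with a GC offset, were chosen after the results they bear on had been seen. Further genes lower in the libraries labelled MHC-II high, chosen here after their values were seen, included several outside the lists. Axl, a receptor tyrosine kinase that takes part in the uptake of dying cells, stood at 60.4 ± 9.4 CPM in the libraries labelled high and 263 ± 84 CPM in those labelled low (adjusted p 0.0237 by edgeR). Ccnd2, a D-type cyclin, stood at 12.5 ± 0.77 and 48.7 ± 13 CPM, and Spint1, a membrane protease inhibitor, at 8.68 ± 2.5 and 55.9 ± 23 CPM. Aldh1a2, an enzyme of retinoic acid synthesis, stood at 0.187 ± 0.086 and 3.74 ± 2.5 CPM, and Dnase1l3, a secreted nuclease, at 0.983 ± 0.61 and 11.1 ± 5.6 CPM. Klrk1 and Cd226, receptors best known from natural killer and T cells, stood at 0.163 ± 0.018 and 0.197 ± 0.074 CPM under the high label and at 3.15 ± 1.0 and 3.61 ± 1.7 CPM under the low label.

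MHC class II RNA was lower in the libraries labelled MHC-II high. B cells in the libraries labelled MHC-II low are argued against, since the 12 B cell markers together rose by 0.315% of the rise of Cd74 (from 2.88 to 12.4 CPM, against a rise of 3020 CPM). An exchange of the 2 labels and a difference between surface protein and RNA, which was not tested here, cannot be told apart. For H2-Aa, H2-Ab1, H2-Eb1 and Cd74, 6 of 6 libraries lay on the side opposite to their label, but this count restates the pattern and decides nothing.

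The library labelled MHC-II low replicate 3 stood apart, and no biological explanation was tested for a single library. Its deviation from the other 2 libraries labelled low had a Spearman correlation of 0.683 with GC content and of -0.112 with exonic length over genes. A GC bias may therefore account for part of the pattern, although the gap between the correlation of the other 2 and its own mean correlation with them fell only from 0.0379 to 0.0218 when the trend over GC content was taken out. Thinning all libraries to 4661030 reads outside rRNA and mitochondria left a gap of 0.028, and thinning with the GC trend taken out left 0.0119. Whether depth, alone or with GC content, accounts for all of it cannot be told apart, since the gaps of 0.028 and 0.0119 lay between the bounds set in advance. The correlation with exonic length also lay between its bounds, and no gap was computed for length.

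Dendritic cell marker genes were lower in the libraries labelled MHC-II high. A lower share of macrophages in the libraries labelled low that raised all other types alike is argued against by the medians of the marker lists. The median of 15 dendritic cell markers differed by -1.85 on the log2 scale from that of 28 markers of neutrophils, endothelium, fibroblasts and epithelium (permutation p 1e-05, the smallest that 100000 resamples give). It differed by -1.69 from that of 53 markers of 9 other cell type lists (permutation p 2e-05, and -2.42 to -1.44 over the markers tested with 1 library left out). Of the 28 markers 13 were fibroblast genes. These permutations shuffled genes, which are not independent replicates, and the dendritic list had been seen to be low beforehand. The p values thus do not measure the spread between libraries, and an unequal rise of other types is not addressed. The medians of 3 B cell (-1.88), 2 T and NK cell (-1.46), 2 mast cell and eosinophil (-3.21) and 13 monocyte markers (-1.01) were also below 0, so that a rise of these types together with dendritic cells is not excluded. The mast cell and eosinophil value rests largely on Ear2 (-6.18), and without labelled low replicate 3 the median of 3 tested markers was -0.743. Dendritic cells inside the gate of the libraries labelled low cannot be told apart from macrophages that express these genes: the 18 macrophage core genes had a median log2 fold change of -0.364, with 4 lower and 2 higher by more than 2 standard errors, but of -0.0278 without labelled low replicate 3, of -0.07 with the GC offset, and of -0.609 with 10 lower without labelled low replicate 2. The gate on F4/80 and CD11b would remove many dendritic cells, lymphocytes and mast cells, and its exclusion of Ly6C many monocytes, while eosinophils can carry F4/80 and CD11b. The sorted MHC class II state itself stays an open biological explanation. Were the 2 labels exchanged, the libraries labelled low would come from the gate for high MHC class II.

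A hypothesis written before its test was that lncRNAs move with their nearest protein-coding gene. Only tested protein-coding genes were searched, so overlap and distance refer to these, and an lncRNA that overlaps an untested gene can count as not overlapping. Over 824 lncRNAs the fold changes of both had a Spearman correlation of 0.35 (permutation p 1e-05, the smallest that 100000 resamples give, and 1.4e-05 adjusted over the 10 sets tested). It was 0.536 for 161 lncRNAs that overlap the gene on the same strand, where reads can be shared, 0.277 for 271 that overlap it on the opposite strand and 0.317 for 392 that do not overlap it. Among the last it was 0.311 for 220 within 10 kb, 0.37 for 120 at 10 to 100 kb and 0.136 for 52 farther away (adjusted permutation p 0.3). With the GC offset it was 0.208 for all and 0.207 for those without overlap (adjusted permutation p 6.2e-05), and without labelled low replicate 3 it was 0.227. Protein-coding genes and their nearest protein-coding gene gave 0.429, and 0.152 with the GC offset. Shared base composition of neighbours may thus account for a part of the relation, and genes are not independent replicates.

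The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The split by label gave 63 genes and the highest of the other 9 gave 0, so that 1 split of 10 gave as many. The 3 other splits that, like the real one, part all 3 batch pairs also gave 0. Groups did not overlap for 2820 genes, 19.9% of those tested, where chance gives 10% for exchangeable libraries. The libraries are not exchangeable: the split of labelled high 1 with labelled low 1 and 3 against the other 3 gave 40.9% with 0 genes called, which points to a structure other than the labels. That split also parted the libraries by their trend over GC content (0.03, 0.21 and 0.82 against -0.26, -0.46 and -0.34 per 10 percentage points). It parted them by rRNA share as well (5.17%, 13.5% and 47.3% against 4.17%, 3.85% and 3.87%). Whether these account for the 40.9% was not tested. The remaining 8 splits gave 2.8% to 6.72%.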
